A study of Homo sapiens with 23 samples.

How the data were processed

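The series compared commercial polyA RNA of human fetal heart with commercial polyA RNA of human adult heart on Agilent 2-colour arrays, in which 2 RNAs labelled with the dyes Cy5 (red) and Cy3 (green) compete for the same spots. Of the 23 arrays, 11 carried fetal RNA in Cy5 and adult RNA in Cy3, 7 carried the opposite dye orientation, 3 carried adult RNA in both dyes and 2 carried fetal RNA in both dyes. The arrays lay on 3 slides. Groups and dyes came from the sample labels. Replicate numbers are accession order and only name an array.

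The deposited values are log10 ratios per spot. Per the labels, the RNA was amplified and labelled by the manufacturer's protocols, the images were processed with Feature Extraction 7.5, and saturated and outlier spots were left out by the authors. The log10 scale and the direction, Cy5 over Cy3, rest on the software's definition of its log ratio and on the dyes in the labels. The 2 orientations carried opposite signs for the same genes, so the authors had not turned the swapped arrays. Which dye normalization and background correction the software applied is not given in the sources used here. Most values were rounded to 0.01 on the log10 scale, which is 0.03 on the log2 scale, and the largest size was 2 on the log10 scale. The median log10 ratio of an array lay between -0.03 and 0. No spot intensities were used, so weak spots could not be filtered and genes could not be matched on signal. The number of arrays limits the precision.

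The table held 1890 probes. GEO's platform annotation paired 1112 of them with 1 gene symbol (1065 genes) and 1 with several, and 777 have no symbol here. Symbols were updated through gene identifiers with the RefSeq table of GRCh38.p14, in which 1106 of the 1113 annotated probes matched. No probe is named from an entry with several genes, and no coordinates are given because the files name no genome build. Between 1726 and 1863 probes were reported per array. A set of 155 spots without a gene had log2 ratios beyond 2-fold on the self arrays, where both dyes carry the same RNA. They are called control-like below, since no gene probe did this.

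Log10 ratios were converted to log2. Fetal against adult was fitted with limma 3.58.1 in R 4.3.3. Each probe's log2 ratio on the 18 arrays with both RNAs was modelled by a dye intercept and an orientation term (1 with fetal RNA in Cy5, -1 with adult RNA in Cy5), followed by eBayes. The orientation term is the log2 ratio of fetal over adult. Probes needed at least 4 values in each orientation, which left 1839. P-values were adjusted by Benjamini-Hochberg, and 0.05 was the threshold. A probe is called at least 2-fold changed when it also had an absolute log2 ratio of at least 1. Errors are standard errors (SE) of the fit unless marked SD. The dye intercept was tested in the same fit. Self arrays were tested against 0 and against each other with limma, for probes with at least 2 values per kind of array.

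The RNA of every array carries the same commercial description, and nothing says that separate preparations were used. The arrays are therefore likely repeated hybridisations of the same 2 RNAs, and the p-values of single probes measure only the spread between arrays. Those of the list tests compare the genes of a list with other genes, and Fisher's exact test counts genes. None of these p-values measures variation between hearts. Averages per slide were fitted as alternatives.

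Of 23 gene lists fixed before the data were examined, the 6 with at least 5 measured genes were tested with limma's cameraPR on the moderated statistics. It used 1 probe per gene (the probe measured on most arrays) and a preset correlation of 0.01. Alternatives were camera with an estimated correlation and the percentile of the list's median among 10000 random lists. Genes are named by a rule fixed at the same time. It took up to 12 genes per direction with the largest ratios among those at least 2-fold changed with the same sign on every measured array. It added up to 4 members of each list, and the 3 largest dye effects in each direction. MCM7, CDKN1A and RPS10 are named outside this rule and were chosen after their values were seen. LAPTM5 and EDN1, which did not pass, are also outside it, as are genes named only in the later sections.

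The fit was tested on simulated data with the real spreads and missing values, in which 200 of 1839 probes were changed. It recovered 37 of 50 probes changed by a log2 ratio of 0.1, 43 of 50 changed by 0.25, 48 of 50 changed by 0.5 and 49 of 50 changed by 1. Of the calls, 3.80% were unchanged probes. For adult self against fetal self, with 1695 probes, 48 of 100 changed by 0.25 and 72 of 100 changed by 0.5 were recovered, and 7.69% of the calls were unchanged probes. In simulated list tests, 94 of 100 lists of 13 genes shifted by 0.5 and 5 of 100 unshifted lists were called. Genes were simulated without correlation, whereas the correlations estimated for the tested lists ran from -0.03 to 0.67. These shares therefore do not hold for lists of correlated genes. The alternatives tried were centring and scaling of arrays, filters on missing values, the dye term, slides, averaging, the samples fitted, the variance model, probes of 1 gene, and leaving out each array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.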

Results

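Transcript ratios between human fetal heart RNA and human adult heart RNA were measured on 23 two-colour arrays from 3 slides. Both RNAs were present on 18 arrays, 11 with fetal RNA in Cy5 and 7 with adult RNA in Cy5, and 5 self arrays carried 1 RNA in both dyes (3 adult, 2 fetal). Each array reported 1726 to 1863 of 1890 probes, of which 1011 to 1103 have a gene symbol. Within an orientation, gene probes correlated between arrays with r of 0.884 to 0.991 across probes, and arrays of opposite orientation correlated with r of -0.944 to -0.866. Probes are not independent replicates. Few genes of the heart's contractile and energy machinery had a probe with a gene symbol. There was 1 gene of the sarcomere list and 1 of fatty acid oxidation, and both were measured. The citric acid cycle and oxidative phosphorylation lists also had 1 gene each, and neither passed the filter on missing values.

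The first comparison asked which transcripts differed in abundance between the fetal and the adult heart RNA. The 5 genes with the largest ratios, CXCL8, HBE1, SELE, EPCAM and SPP1, were all higher in the fetal RNA. The neutrophil-attracting chemokine CXCL8 was 25.6-fold higher in the fetal RNA (log2 ratio 4.68 ± 0.07, SE, 18 of 18 arrays, limma adjusted p = 3.17e-21). The embryonic globin HBE1 was 23.1-fold higher (4.53 ± 0.05, 18 of 18 arrays), and E-selectin (SELE), an adhesion molecule of activated endothelium, was 18.5-fold higher (4.21 ± 0.06, 15 of 15 arrays). EPCAM, an epithelial adhesion molecule, was 12.7-fold higher (3.67 ± 0.09), and osteopontin (SPP1), a secreted matrix phosphoprotein, was 10.3-fold higher (3.37 ± 0.04).

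Further genes were among the 12 with the largest ratios toward the fetal RNA. The monocyte chemokine CCL2 had a log2 ratio of 2.97 ± 0.02, the granulocyte growth factor CSF3 2.92 ± 0.03, the interleukin-33 receptor IL1RL1 2.96 ± 0.06 and the chemokine CXCL6 was 5.66-fold higher. Of the 7 arrays with adult RNA in Cy5, replicate 7 had the smallest SD of log2 ratios across gene probes (0.74) and the lowest ratios of CXCL8 (3.92), HBE1 (3.79), SELE (3.75), EPCAM (3.52), SPP1 (2.86), CSF3 (2.56) and CDH16 (2.56), among others. Of 18 leukocyte genes, a list drawn up after the largest ratios had been seen, 4 rose and 11 fell. The potassium channel KCNJ16, which the kidney tubule expresses, reached 3.03 ± 0.12 and the kidney cadherin CDH16 2.88 ± 0.02. Of 16 other kidney genes, also listed after the largest ratios had been seen, 11 rose, 2 fell and 3 did not pass. The globin HBM reached 2.79 ± 0.04. These 12 genes were higher in the fetal RNA on every array that measured them.

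Fewer genes were at least 2-fold higher in the adult RNA, 9 against 91 in the fetal RNA. The interferon-induced gene IFI27 was 6.26-fold higher in the adult RNA (log2 ratio -2.65 ± 0.01, limma adjusted p = 2.12e-29). TIMP4, a metalloproteinase inhibitor, was 4.35-fold higher (-2.12 ± 0.02), and CMAS, which activates sialic acid, was 3.47-fold higher (-1.80 ± 0.02). The glycolytic enzyme GAPDH (-1.50 ± 0.01) and the cytoskeletal actin ACTB (-1.50 ± 0.01) were also higher in the adult RNA. One of the 3 ACTB probes gave only -0.38 ± 0.01, while another gave -1.48 ± 0.01. PPP1R1C, a phosphatase inhibitor subunit, had -1.45 ± 0.03. The mitochondrial ADP/ATP carrier SLC25A5 (-1.04 ± 0.01), KLHL24 (-1.03 ± 0.01) and the dipeptidase PEPD (-1.003 ± 0.01) lay next to the 2-fold limit. These 9 genes were higher in the adult RNA on every array that measured them.

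**Figure D1:**
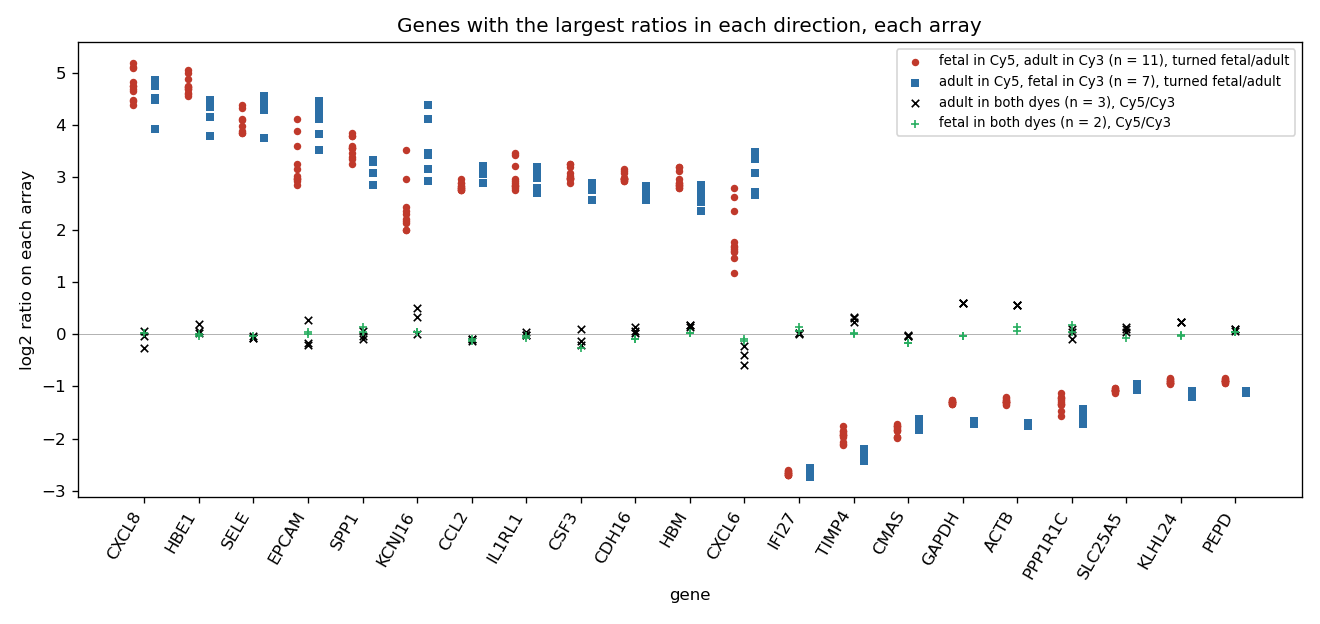
Log2 ratio on each array (y axis) for the 12 genes with the largest ratios toward the fetal RNA and the 9 at least 2-fold higher in the adult RNA (x axis); circles and squares are the arrays with both RNAs, turned to fetal over adult, and crosses and plus signs are Cy5 over Cy3 on the self arrays. All fetal-adult values of CXCL8 and HBE1 lay above those of the self arrays, and all values of IFI27 lay below them.

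Among 1095 tested probes with a gene, 961 (87.8%) changed, 456 higher in the fetal and 505 higher in the adult RNA. This balance turned to 508 and 444 when arrays were centred, and to 510 and 438 when they were centred and scaled. Centring used the median of all probes of an array, with and without a gene, so it did not set the gene probes to a median of 0. The mean ratios of the dye orientations had opposite signs for 196 gene probes, of which 100 were called, 49 as higher in the fetal and 51 as higher in the adult RNA. None of these reached 2-fold. At least 2-fold changes were unequally divided: 93 probes (91 genes) were higher in the fetal RNA and 10 probes (9 genes) in the adult RNA. All 103 kept their sign on every measured array. The median SE was 0.02, so small ratios passed the test. A ratio above the largest value of the same probe on any self array was found for 711 of the 961. Gene probes did not form a single peak around 0. Between log2 ratios of -1 and -0.5 lay 259 of them, all called, which were 51.3% of the probes called higher in the adult RNA. RPL21, CDKN1C, CCND2 and FOSL2, named below, are among them. Between -0.5 and -0.25 only 60 were called. Over all 1839 tested probes, 1592 changed and 210 changed at least 2-fold, 121 higher in the fetal and 89 in the adult RNA. The at least 2-fold changes in these directions were 108 and 137 without slide 1, and 115 and 136 on slide 3 alone. Of the 155 control-like spots, 154 were called, all as higher in the adult RNA and 22 at least 2-fold, so the counts for gene probes are the ones to read. With a test against a 1.5-fold change, 410 gene probes passed, 172 higher in the fetal and 238 in the adult RNA.

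**Figure D2:**
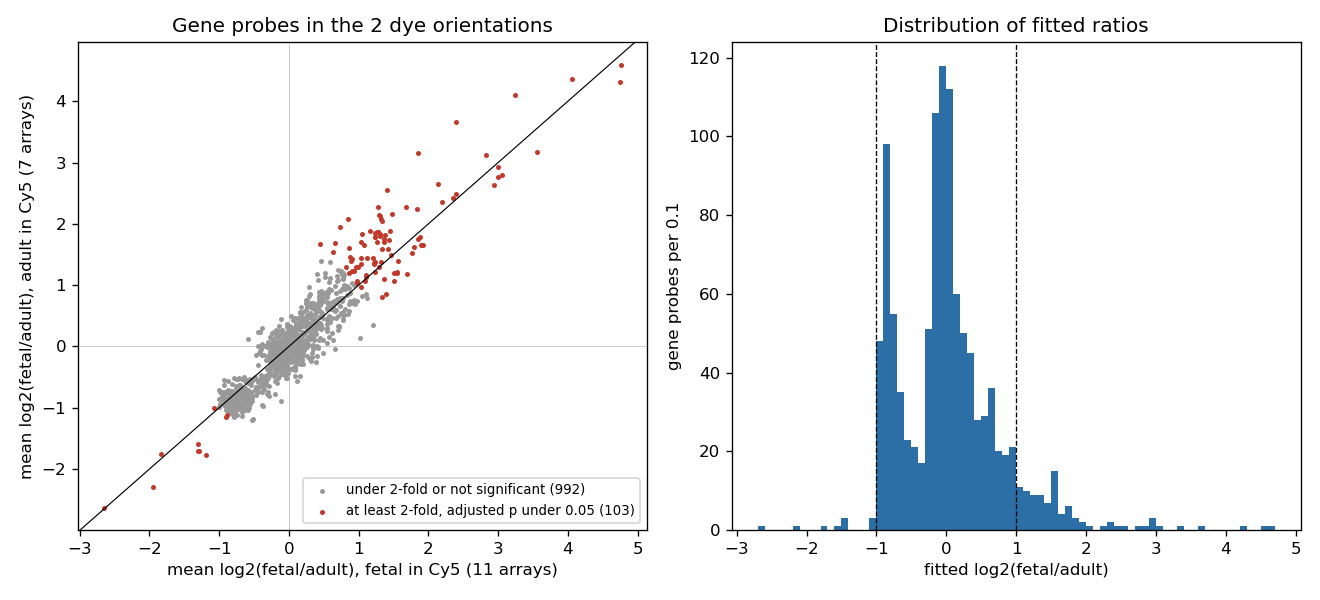
Left, mean log2 ratio of fetal over adult for each gene probe with fetal RNA in Cy5 (x axis, 11 arrays) against adult RNA in Cy5 (y axis, 7 arrays), with the line of equality; right, number of gene probes per 0.1 of fitted log2 ratio, with dashed lines at 2-fold. The 103 probes in red changed at least 2-fold, and a second peak lies between -1 and -0.5.

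Extracellular matrix genes were higher in the fetal RNA: 11 of 13 measured genes rose, none fell and 2 did not pass (11 when adjusted over the list alone). Periostin (POSTN), a matrix protein of developing valves, had a log2 ratio of 1.71 ± 0.02, and the laminin chain LAMB1 1.08 ± 0.01. The proteoglycan VCAN had 0.34 ± 0.01 and the collagen COL18A1 0.17 ± 0.01. The list stood above other genes (median 0.84, cameraPR adjusted p = 0.000288). That call was lost with an estimated correlation, over the 10 members measured on all 18 arrays, where the adjusted p was 0.272. None of the 6 lists passed in that test, and its lowest unadjusted p was this list's, 0.0454.

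All 6 measured erythroid genes rose, 4 of them at least 2-fold, and 6 when adjusted over the list alone. HBE1 and HBM had the largest ratios of the list. The embryonic globin HBZ reached 0.52 ± 0.03 and carbonic anhydrase CA2 0.29 ± 0.02. The median was 1.18 and the adjusted p of cameraPR was 0.0405, against an adjusted p of 0.438 with an estimated correlation.

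Of 13 measured cell cycle and DNA replication genes, 10 rose and 3 fell, and 13 passed when adjusted over the list alone. Thymidylate synthase TYMS (2.44 ± 0.05) and the mitotic spindle gene DLGAP5 (1.98 ± 0.09) were highest in the fetal RNA. Cyclin D2 (CCND2) was higher in the adult RNA (-0.84 ± 0.02). CKS1B, at -0.02 ± 0.01, had mean ratios of opposite sign in the dye orientations, and its fitted sign turned when arrays were centred (0.03). The third gene counted as falling, the replication helicase subunit MCM7 (-0.02), also had orientation means of opposite sign (0.03 and -0.06). The list's median was 0.61, at the 99.7th percentile of random lists, but cameraPR did not call it (adjusted p = 0.277).

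Immediate early, stress and acute phase genes were mostly higher in the fetal RNA, with 9 of 11 rising and 2 falling, and 11 passing when adjusted over the list alone. The chaperone DNAJB1 had a log2 ratio of 0.96 ± 0.02 and the early growth response gene EGR3 0.94 ± 0.05. Lower in the fetal RNA were FOSL2 (-0.59 ± 0.01) and CCN1 (-0.05 ± 0.01), whose call was lost when arrays were centred. For CDKN1A (0.06), counted as rising, the orientation means had opposite signs (0.26 and -0.15). A second FOSL2 probe gave the opposite sign (0.12 ± 0.03). The list passed cameraPR (adjusted p = 0.0124), but not with an estimated correlation (adjusted p = 0.438). It also failed without slide 1, 2 or 3, with adjusted p of 0.111, 0.0576 and 0.0719.

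Imprinted and fetal growth genes went both ways, 4 of 5 rising and 1 falling, and 5 passing when adjusted over the list alone. IGF2BP1, an mRNA-binding protein of fetal tissues, had a fitted ratio of 1.06 ± 0.03, from 0.45 ± 0.13 (SD, n = 11) with fetal RNA in Cy5 and 1.67 ± 0.12 (SD, n = 7) with adult RNA in Cy5, and reached 0.96 in size on a self array. MEST had 0.78 ± 0.01. DLK1 had a fitted ratio of 0.31 ± 0.01 that rested on 1 orientation: it was 0.66 ± 0.06 (SD, n = 9) with fetal RNA in Cy5 and -0.04 ± 0.01 (SD, n = 7) with adult RNA in Cy5. The growth inhibitor CDKN1C was higher in the adult RNA (-0.68 ± 0.01). The list did not pass (cameraPR adjusted p = 0.527). Ribosomal protein genes were divided, 3 rising, 4 falling and 1 not passing of 8, and 7 passing when adjusted over the list alone. They ran from RPL31 (0.81 ± 0.01) and RPL6 (0.18 ± 0.01) to RPL7A (-0.19 ± 0.01) and RPL21 (-0.66 ± 0.01). RPL6 lay below its largest size on a self array (0.30). RPS10 (-0.01), counted as falling, had orientation means of opposite sign (-0.12 and 0.09). All 5 RPL21 probes lay between -0.66 and -0.58. The list did not pass (cameraPR adjusted p = 0.847), with a median of -0.01 below 0 and a mean of 0.02 and a test direction above 0.

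**Figure D3:**
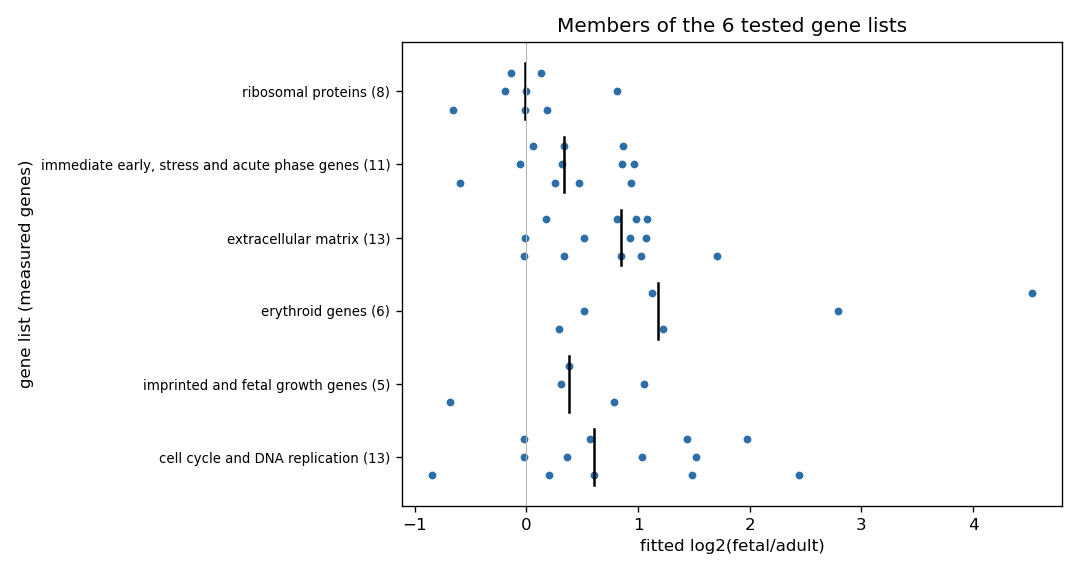
Fitted log2 ratio of fetal over adult (x axis) for each measured gene of the 6 tested lists (y axis, with the number of genes); points are genes, spread vertically only for visibility, and bars are list medians. The bars of the erythroid and extracellular matrix lists lie at 1.18 and 0.84, and that of the ribosomal list at -0.01.

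The remaining lists had too few measured genes to test. Slow skeletal troponin I (TNNI1), the fetal heart's troponin I isoform, was higher in the fetal RNA (1.39 ± 0.03). The glucose transporter SLC2A1 was also higher (1.01 ± 0.01), whereas GAPDH and lactate dehydrogenase LDHA (-0.14 ± 0.01) were lower. The peroxisomal racemase AMACR, from the fatty acid list, was higher in the adult RNA (-0.44 ± 0.04). Heart development regulators were all 3 higher in the fetal RNA: SOX11 (0.46 ± 0.03), TBX20 (0.15 ± 0.03) and JAG1 (0.08 ± 0.01). The ratios of TBX20 and JAG1 lay below their largest sizes on a self array (0.20 and 0.23). Each was higher in the adult RNA on 3 arrays, and the call of TBX20 was lost on slide 2 alone. The potassium channel KCNJ2 had 0.13 ± 0.01, also below its largest size on a self array (0.33). The neuronal genes STMN2 (0.63 ± 0.05) and GAP43 (-0.10 ± 0.03) went apart, and the call of GAP43 was lost when arrays were centred.

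Markers of other cell types were few. Of 4 genes of the macrophage and other leukocyte list, CXCL8, CCL2 and S100A9 (0.41 ± 0.01) rose. LAPTM5, a lysosomal protein of blood cells, was at -0.05 ± 0.03 and did not pass. Cytokines also induce CXCL8 and CCL2, so their rise need not mark leukocytes. The lymphocyte gene CD69 reached 0.48 ± 0.03, TAP1 of antigen presentation 0.16 ± 0.01, and the fibroblast genes FAP 0.41 ± 0.03 and TCF21 0.08 ± 0.02. Those of TAP1, FAP and TCF21 lay below their largest sizes on a self array (0.33, 0.47 and 0.47). SELE was the 1 measured endothelial gene, and the smooth muscle gene SYNPO2 was higher in the adult RNA (-0.24 ± 0.06). For TAP1 and TCF21 the orientations gave means of opposite sign. Endothelin (EDN1) was at 0.00 ± 0.01 and did not pass. No adipocyte gene and no gene of the liver and lung list was measured.

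Fitted within each slide, the ratios correlated across gene probes with r of 0.989 to 0.995. CXCL8 had 4.98, 4.74 and 4.37 on slides 1, 2 and 3, and IFI27 had -2.66, -2.61 and -2.64. Ratios on slide 1 were higher for KCNJ16 (3.72, 2.67 and 2.74), CXCL6 (3.01, 2.16 and 2.24), DLGAP5 (2.43, 1.62 and 1.79) and EPCAM (4.11, 3.38 and 3.53). The ratio differed between slides for 251 of 1069 gene probes, with a median range of 0.08 log2 units. At least 2-fold gene calls on slide 1 alone were 118 higher in the fetal and 21 in the adult RNA, against 85 and 9 on slide 2 and 91 and 8 on slide 3. The SD between arrays was 0.08 (median over gene probes) with fetal RNA in Cy5 and 0.05 with adult RNA in Cy5. Ratios were larger with adult RNA in Cy5 (major axis slope 1.18). With fetal RNA and with adult RNA in Cy5, the mean ratios were 2.40 and 3.65 for KCNJ16, 1.85 and 3.16 for CXCL6, 1.40 and 2.55 for DLGAP5 and 3.25 and 4.10 for EPCAM.

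The self arrays gave the background of the measurement and the effect of the dyes. No gene value on them was beyond 2-fold, whereas 6.90% to 18.01% of gene values were on the arrays with both RNAs. The dye term of the arrays with both RNAs was called for 792 of 1095 gene probes and never reached 2-fold (-0.66 to 0.44). Its largest values toward Cy5 were those of RASSF7 (0.44 ± 0.01), the elastase CELA1 (0.43 ± 0.01) and the kinase CDK6 (0.39 ± 0.03). Toward Cy3 they were those of CXCL6 (-0.66 ± 0.11), KCNJ16 (-0.63 ± 0.12) and the actin-severing protein SCIN (-0.62 ± 0.06). On the adult and fetal self arrays KCNJ16 went the other way (0.28 and 0.03). CXCL6 (-0.41 and -0.12) and SCIN (-0.44 and -0.20) kept the direction, and none of these genes passed on the adult self arrays. Fetal over adult ratios, with the dye term removed, were 0.58 ± 0.01 for RASSF7, 0.78 ± 0.01 for CELA1, -0.50 ± 0.03 for CDK6 and 1.46 ± 0.06 for SCIN. In size, those of RASSF7 and CDK6 lay below the largest values of these probes on a self array (0.60 and 0.56). With fetal RNA and with adult RNA in Cy5, the mean ratios were 1.01 and 0.14 for RASSF7 and -0.11 and -0.89 for CDK6.

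Whether the dye effect depended on the RNA was asked with the self arrays alone. With adult RNA in both dyes, 469 of 1100 gene probes differed from 0, and with fetal RNA in both dyes 58 of 1001 did. That test had 2 fetal arrays, and over all probes its count of 107 became 0 in limma when arrays were centred, with 546 at an unadjusted p under 0.05. Over all probes, the adult count of 882 fell to 586, 159 and 157 without replicate 1, 2 or 3. Adult and fetal self arrays differed for 352 of 998 gene probes (limma). Over all probes the count was 516, and it was 250 and 237 without fetal self replicate 1 or 2 and 333 without adult self replicate 2. The lowest p belonged to GAPDH, with a Cy5 over Cy3 log2 ratio of 0.60 on the adult and -0.03 on the fetal self arrays. Across probes, the mean ratios of both kinds of self array correlated with r of 0.129, while single arrays of the same RNA correlated with r of 0.757 to 0.774 (adult) and 0.529 (fetal).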

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

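Chosen only after the result was seen were both tests of a dye or spot effect, both tests on the gene probes between log2 ratios of -1 and -0.5, and the correlation and slope of the self arrays. The kidney, cytokine and leukocyte lists were drawn up after the largest ratios had been seen, from genes whose ratios had not been, except LAPTM5.

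The number of changed probes was set against 100 splits of the 18 arrays into 11 and 7, the real one included. Only the real split called as many (1 of 100), with 1592 changed probes against 1268 in the highest other split, which held 0 of the 7 adult-in-Cy5 arrays in their place and so nearly mirrored the real one. The count of at least 2-fold changed probes was likewise reached by 1 of 100 splits, with 210 against 97. Arrays of opposite orientation carry opposite signs, so splits that mix them largely cancel the ratios. The comparison therefore shows only that the calls follow the dye labels. It adds no support for a difference between fetal and adult hearts beyond these 2 RNAs.

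Some arrays lay apart from the others of their group of 7 with adult RNA in Cy5, by the ratio of the gap to the nearest array to the whole range. Chance alone gives this in about 1 in 20 sets, and 6 of 69 sets showed it. Replicate 7 had the lowest log2 ratio of CXCL8 (3.92, next 4.48), SELE (3.75, next 4.29), CSF3 (2.56, next 2.76) and CDH16 (2.56, next 2.72). It was also lowest for HBE1 (3.79, next 4.15) and SPP1 (2.86, next 3.09), and had the smallest SD across gene probes of the 7 (0.74). DLK1 (-0.066 on replicate 7, -0.033 on the next) and RASSF7 (0.17 on replicate 2, 0.13 on the next) differed by 1 rounding step only.

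Adult and fetal self arrays differed in the Cy5 over Cy3 ratio for 516 of 1695 probes, by limma's test of the difference. The adult minus fetal difference in log2 ratio was 0.63 for GAPDH, 0.48 for CDK6, 0.37 for CELA1 and 0.36 for RASSF7. Across 996 gene probes the mean ratios of both kinds of self array correlated with r of 0.129, and the slope of the dye term of the arrays with both RNAs on the mean of the self arrays was 1.61. In spots that no comparison of genes used, 155 control-like spots had a median log2 ratio of -4.62 on the self arrays.

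Among the genes with large ratios toward the fetal RNA, 5 that kidney or epithelium expresses were picked for that direction (EPCAM, SPP1, KCNJ16, CDH16 and FXYD2), and of 16 further kidney genes SLC3A1 (1.69), HSD11B2 (1.67) and CLDN10 (1.57) were highest. The first 5 had a lowest ratio of 0.96 on any array (FXYD2) and a largest size of 0.50 on any self array. They kept 1 sign in both orientations, which a dye effect alone does not give. Their selection for large ratios largely fixed this outcome, and a spot effect of only 1 of the RNAs is not excluded. Kidney RNA in the fetal RNA may be a source, since the further genes had a median of 0.86, at percentile 100 of 10000 random lists, but MME (-0.42) and CDHR5 (-0.52) were lower and SLC7A9 (0.01) did not pass. Of 10 further epithelial genes 6 rose and 2 fell (median 0.36, percentile 96.7), and of 11 liver genes 2 rose and 7 fell (median -0.26, percentile 6.42). The random lists were not matched on signal, heart expression of the listed genes was not counted, and expression of these genes by fetal heart itself stays open and untested.

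Among the genes with large ratios toward the fetal RNA, 10 that cytokines induce were picked for that direction (CXCL8, SELE, CCL2, CSF3, VCAM1, CXCL6, CXCL11, ICAM1, IL1RL1 and ADAMTS4), while the interferon-induced IFI27 (-2.65) went the other way. A dye effect alone does not give 1 sign in both orientations. The lowest ratio of these 10 on any array was 0.93 (CXCL11), and their largest size on any self array was 0.60. Because they were picked for large ratios, this outcome was largely fixed by the selection. A spot effect that only 1 of the RNAs gives would not show on self arrays and is not excluded. The 18 leukocyte genes had a median of -0.11 (bootstrap interval over genes -0.33 to -0.04), and 4 rose and 11 fell. They ran from CD300LB (-0.77) to C5AR1 (0.88). The median lay at percentile 19.46 of random lists, so the leukocyte genes as a set did not rise. Without intensities, weak spots among them cannot be told from unchanged genes. The list therefore cannot decide whether more leukocytes were a source. The list mixes genes of several leukocyte types, so more leukocytes of 1 type are not excluded. S100A9 (0.41) and CD69 (0.48), leukocyte genes outside this list, rose. A rise of cytokine-induced genes beyond the picked ones, though not of all of them, may be a candidate explanation, since 11 further genes, among them CFB (1.48), NFKBIZ (1.19) and BCL3 (-0.08), had a median of 0.67, at percentile 99.81 of random lists. Development, the state of the donor tissue and its handling before extraction stay open and untested.

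Between log2 ratios of -1 and -0.5 lay 259 gene probes (23.7%), at the edge of the 2-fold limit. Normalization of single arrays, slides or 1 dye orientation is excluded as the only source, since on each of the 18 arrays at least 18.7% of gene probes lay in that range. On a self array at most 0.555% did. With 1 RNA in both dyes few ratios could be that large, so the self arrays add nothing here. The comparison of the 18 arrays cannot address a normalization effect shared by all of them, which stays open. Weak spots of genes with little RNA in either heart may contribute, and this stays open because no intensities were used. Of 22 genes of families restricted to other tissues, such as MC5R (-0.86) and OPN1MW (-0.85), 40.9% lay in the range, against 55.8% of 43 broadly expressed genes, such as CANX (-0.88) and YWHAB (-0.83), with p = 0.301 in a two-sided Fisher's exact test. A true difference between the RNAs also stays open and was not tested.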

How the results depend on the processing

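Chosen after seeing the data were the fits on gene probes only, without control-like spots, with values of 0 and at the limits missing, and without the 2 arrays of the largest residual spread. No paired analysis was possible because replicate numbers are accession order only. Arrays share slides, and 1604 probes changed with a dye intercept for each slide, 1605 with slide as a random block and 1476 with 1 dye-balanced mean per slide. For 63 named genes and 41 settings, not all of which gave a value for genes with missing values, 2518 gene and setting pairs kept direction and call, 43 lost the call and 2 reversed. In the settings that gave them a value, 37 genes kept both. Most of the lost calls came from the test against a 1.5-fold change, which asks for more than a difference from 0. Every gene that lost a call lost it there. Only CCN1, CKS1B, GAP43, SYNPO2, TBX20 and TCF21 also lost it in another setting. The CKS1B log2 ratio reversed to 0.026 with arrays centred and to 0.020 with arrays centred and scaled (adjusted p of 0.00202 and 0.0205, and 0.000814 to 1 over all settings). Centring on the median of all probes moved the median of gene probes from -0.02 to 0.02 and turned their balance to 508 higher in the fetal and 444 in the adult RNA. Changed probes numbered 1366 (no dye intercept) to 1607 (fewer values needed) where all kinds of probe were fitted per probe, and 1556 to 1598 without any 1 array. With fewer tests, they numbered 926 as means over the probes of a gene and 964 with gene probes only. Against a 1.5-fold change 617 passed. At least 2-fold changes numbered 200 to 220 without any 1 array, 98 as means per gene and 103 with gene probes only. Without slide 1 they numbered 245 (108 higher in the fetal and 137 in the adult RNA), with 83 and 8 among gene probes, and on slide 3 alone 251 (115 and 136), with 91 and 8. Centring and scaling gave 321 (127 higher in the fetal and 194 in the adult RNA), although gene probes were 104, 97 and 7; the cause was not tested. Without control-like spots 1441 and 188 were called, with values of 0 and at the limits missing 1568 and 200, and without the 2 widest arrays 1597 and 220.

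The dye effect was called for 312 probes on the 5 self arrays, fitted with 1 mean over both RNAs. The 3 adult self arrays alone gave 882, so the number of arrays by itself does not account for the 312. Adult and fetal self arrays differed for 516 probes, and the cause of the lower count was not tested. Calls on the fetal self arrays were 0 when centred (546 at an unadjusted p under 0.05 in limma) and 381 with the variance pooled over the 5 self arrays; the cause was not tested. Adult self calls were 157 to 586 without 1 array, that is 586, 159 and 157 without replicate 1, 2 and 3. Calls between adult and fetal self arrays were 237 to 427, with 250 and 237 without fetal self replicate 1 and 2 and 333 without adult self replicate 2. A lone fetal array was assumed to vary like the adult ones. With an estimated correlation, camera called 0 of 6 lists, with adjusted p of 0.272 for extracellular matrix, 0.438 for erythroid and 0.438 for immediate early genes. Over the other settings with a p, these ran from 5.47e-05 to 0.000431, from 0.0110 to 0.0400 and from 0.00736 to 0.111. Immediate early genes had 0.111, 0.0576 and 0.0719 without slide 1, 2 and 3, and percentile 96.58 among random lists. The cell cycle list, not called by cameraPR, reached percentile 99.66. The cause of these differences was not tested. Without intensities, the limit set by signal over background is unknown.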

Other observations

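The genes in this part were chosen after their values were seen, and no test was chosen for them beyond the limma fit of all probes. Among them, 5 genes were higher in the fetal RNA on all 18 arrays: ANLN, which acts in cytokinesis, had a log2 ratio of 2.40 ± 0.07, the kinetochore genes SPC25 1.78 ± 0.10 and NDC80 1.54 ± 0.05, and the spindle genes ASPM 1.57 ± 0.07 and SPAG5 1.51 ± 0.04. Also higher in the fetal RNA were the Wnt pathway factor LEF1 (1.72 ± 0.07), the homeobox gene HOXB5 (1.28 ± 0.07), the nuclear receptor NR2F1 (1.14 ± 0.03, 15 arrays) and CYP26B1, which breaks down retinoic acid (1.12 ± 0.01). The growth factor binding protein IGFBP3 (1.65 ± 0.01), the proteoglycan GPC6 (1.70 ± 0.04) and fast skeletal troponin I TNNI2 (1.35 ± 0.03) were higher too. These genes are single examples, and no gene group was tested.

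The interferon-induced genes CXCL11 (1.82 ± 0.12) and GBP3 (0.48 ± 0.02) were higher in the fetal RNA on all 18 arrays. The probes of IFI16 (0.14 ± 0.01 and 0.06 ± 0.01) and IRF7 (-0.15 ± 0.01) were higher in the fetal RNA on 7, 7 and 11 of 18 arrays, so their direction changed with the dye orientation. The adhesion molecules VCAM1 (2.27 ± 0.03) and ICAM1 (1.81 ± 0.02, 10 arrays) were higher in the fetal RNA. The largest ratios of spots without a gene symbol were 4.04 ± 0.02 toward the fetal and -3.67 ± 0.08 toward the adult RNA.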
